A study of Mus musculus with 4 samples.

How the data were processed

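Blood mononuclear cells were measured in 4 libraries, 1 per group, grouped by the treatment and time that the labels give. The deposited files hold, for each library, a matrix of UMI counts per gene and cell, with no normalization. Per the submitters' processing notes, Cell Ranger, Seurat and mm10 were used, and their versions and roles are not given in the sources used here. The deposited cells held at least 301 detected genes and less than 15.0% mitochondrial UMIs, so some cells had been removed by the authors before deposit. The matrices list 16152 gene names, the same in each library. Of these, 12518 match a mouse gene symbol, while 28 begin with RT1-, the rat name of the major histocompatibility complex. A further 1691 begin with AABR07, 238 begin with RGD and 0 begin with H2-. The barcode lists could not name the matrix columns in the control library (4340 barcodes for 14569 columns) or at 24 h (11663 barcodes, identical to those of 12 h, for 12588 columns), so cells were taken from the matrix columns and no barcode was used. No cell of one library had the counts of a cell in another (0 pairs).

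Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, 12073 in the control library, 11027 at 12 h, 11371 at 24 h and 13561 at 96 h. Scrublet, run per library in scanpy 1.11.5, marked 5.49%, 5.11%, 4.07% and 4.66% of them as doublets, which were removed. A platelet-like cluster of 23, 41, 48 and 27 cells was also left out. Cells of the 4 libraries were clustered together by the Leiden method at resolution 1.0, with 15 neighbours on 30 principal components of 2000 variable genes. Immunoglobulin and T cell receptor variable segments and mitochondrial, ribosomal and haemoglobin genes were left out of clustering. Clusters were named from fixed marker genes, with at least 3 markers detected. The scoring rule that turns markers into names was set after the data were seen, and it kept 2 clusters unnamed because a second lineage scored above 50% of the first. Classical monocyte-like clusters rest on 3 detected markers, Csf1r, Fn1 and Lyz2. Software was python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

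UMIs were summed per library and class and scaled to CPM, which sets each class total to the same sum. Each pancreatitis library was compared with the control library where both held at least 50 cells of the class. Levels have exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals, and ratios of levels exact conditional binomial intervals, all at 95%. Where a level is printed without its own interval, the interval of the ratio covers both levels. A gene at 0 UMIs in one library was set to a floor of 3 counts in that library, and its ratio rests on that floor. In list medians such members enter at that floor ratio. Genes counted as at least 2-fold higher or lower had at least 50 CPM in either library and at least 20 UMIs over both. This count describes size and is not a test. Depth sets the precision, and the class sums drew on 48601130 UMIs in the control library, 53421859 at 12 h, 66329918 at 24 h and 69641005 at 96 h.

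The design, the comparisons, the marker genes, the gene lists, the rule for named genes and most alternatives were set before the data were examined. For each time and class the rule names the 3 genes with the largest and the 3 with the smallest ratio, ranked by the interval bound nearest to 1. It asks for at least 50 CPM in either library, 20 UMIs over both, and at least 25% of the highest class's level where the gene is higher, a guard against free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, Xist, Y-linked genes and unnamed gene models were excepted. The counts of genes at least 2-fold higher or lower used neither this guard nor these exceptions, so free RNA of other cells can enter them. From each list the rule takes the members with the largest and smallest ratio. Other list members were chosen after their values were seen, namely Stmn1, Mki67, S100a8, RT1-Da, Cd74, Il1b, Cxcl2, Nfkbia, C1qa, C1qb, Apoe and Ifit3 in monocyte-like cells. Lyz2 in B-like cells, Fn1 and Lyz2 in nonclassical monocyte-like cells, RT1-Ha, Tubb5 and B-like cluster 23 were singled out in the same way.

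The lists were acute inflammation, neutrophil granule proteins, type I interferon response, class II presentation, immediate early genes, heat shock, glucocorticoid response, NF-kB targets, cell cycle, cytotoxic effectors, naive and recirculating lymphocyte, T cell activation and checkpoint, alternative activation and efferocytosis, chemokine receptors and adhesion, glycolysis and hypoxia, oxidative phosphorylation, immunoglobulin constant regions and B cell activation. Lists for acinar, erythroid, platelet and endothelial RNA stood for other cell types. The class II list under rat names was added after the data were seen. A member counted as measured with at least 20 UMIs over both libraries, and as higher or lower at 1.5-fold. Each median was placed among 10000 random lists of the same size drawn from 20 expression bins.

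Alternatives were a stricter cell filter (at least 500 genes and at most 5% mitochondrial UMIs), no cell filter, doublets kept, resolution 2.0, clustering on marker genes only, clustering per library, platelets kept, median-of-ratios scaling, a mean over cells of counts per 10000, thresholds of 10 and 200 CPM, sums thinned to the smaller total, at least 100 UMIs per list member, and totals without haemoglobin, immunoglobulin, mitochondrial and ribosomal genes. T-like cells without cluster 5, B-like cells without cluster 23 and classical monocyte-like cells without clusters 3 and 24 were added after the data were seen. The steps were tested on simulated counts for T-like and classical monocyte-like cells at 12 h. In each, 99 of 100 genes made 3-fold different were called at 2-fold, 0 of 100 made 1.5-fold different, and 0 unchanged genes. The simulated counts held counting noise only, with no differences between animals or libraries. They therefore say nothing about false calls from such differences in these unreplicated libraries.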

Results

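Mononuclear cells of peripheral blood, separated on a Ficoll density gradient, were profiled by droplet-based 5′ single-cell RNA sequencing before and during cerulein-induced acute pancreatitis. Cerulein is a cholecystokinin analogue whose repeated injection overstimulates pancreatic acinar cells and is a standard way to bring on acute pancreatitis in rodents. The labels give wild-type C57BL/6J mice and 7 intraperitoneal injections. The control library was taken at 0 h, the libraries of 12 and 24 h stand for the initial phase, and the library of 96 h for recovery, a time that the series' design text gives as 168 h. Each time had 1 library, and how many animals went into each is not given in the labels. The files held 14569 cells and 62481134 unique molecular identifiers (UMIs) at 0 h, 11663 cells and 60515205 UMIs at 12 h, 12588 cells and 76597006 UMIs at 24 h, and 14560 cells and 79516878 UMIs at 96 h. The median cell had 3571, 4038, 4861.5 and 4728 UMIs in that order. After filtering, 11387, 10423, 10860 and 12902 cells were used.

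The comparisons ask how the makeup and the expression of circulating immune cells in each pancreatitis library differed from those of the control library. With 1 library per time there is no replicate check on any difference, so no p-value is given. A ratio describes a pair of libraries, and its 95% interval covers counting error only. Levels are CPM, the UMIs of a gene scaled to the same total of UMIs in every class sum. Cell classes were rebuilt by clustering and carry the suffix "-like", because they rest on fixed markers and not on an annotation by the authors. The gene names in the files include rat names, with 28 beginning with RT1- and 0 with H2-, although the labels give mice, so genes are named exactly as the files name them and no coordinates are given. Other cells' RNA differed between libraries. Genes named for haemoglobin stood at 115 CPM in all cells of the control library, 340 at 12 h, 64.1 at 24 h and 145 at 96 h. Platelet genes summed to 8.62, 16.9, 14.4 and 6.86 CPM, and pancreatic acinar genes to below 1 in each library, with 0.861 at 12 h as the highest value.

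Classical monocyte-like cells and neutrophil-like cells held larger shares of the blood mononuclear cells in the early pancreatitis libraries, and T-like cells a larger share at 96 h. Classical monocytes are the inflammatory monocytes that leave the bone marrow and enter injured tissue. They made up 4.91% of cells (4.52 to 5.32) in the control library, 6.12% (5.67 to 6.60) at 12 h, 22.98% (22.2 to 23.8) at 24 h and 6.47% (6.05 to 6.91) at 96 h, with exact binomial intervals here and for all shares. Nonclassical monocyte-like cells, which patrol the vessel wall, held 30.6% (29.8 to 31.5), 28.8% (27.9 to 29.7), 19.2% (18.5 to 19.97) and 9.59% (9.09 to 10.1), and their ratio at 12 h was 0.510 with the stricter filter. T-like cells held 26.9% (26.1 to 27.8), 18.6% (17.9 to 19.4), 21.0% (20.2 to 21.8) and 42.5% (41.7 to 43.4).

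The share of classical monocyte-like cells at 24 h was 4.68 times that of the control library (4.29 to 5.11). The size of this ratio depended on how cells were grouped. It was 10.6 with the stricter cell filter, 2.46 with doublets kept, 2.44 when cells were clustered on marker genes only and 1.51 without clusters 3 and 24, which were held almost wholly by the libraries of 24 and 12 h. The ratio at 12 h was 1.25 (1.12 to 1.39), with 8.07 under the stricter filter and 0.0772 without those clusters. At 96 h it was 1.32 (1.19 to 1.46), with 2.74 under the stricter filter and 0.970 with marker genes only. Neutrophil-like cells, most of which a density gradient removes, held 0.281% (0.192 to 0.397) in the control library against 2.38% (2.10 to 2.69) at 12 h, a ratio of 8.47 (5.87 to 12.2), and 3.01% (2.70 to 3.35) at 24 h, a ratio of 10.7 (7.46 to 15.4). They held 0.194% (0.125 to 0.286) at 96 h. With the stricter cell filter, which kept 562 control cells, the neutrophil ratios were 1.09, 1.53 and 0.187. Among all monocyte-like cells the share was 35.5%, 34.9%, 42.2% and 16.1%, with a ratio of 1.19 (1.15 to 1.23) at 24 h and 0.452 (0.432 to 0.474) at 96 h. The ratio at 24 h was 0.919 with the stricter filter, the opposite direction.

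NK-like cells held 3.78% (3.43 to 4.14) in the control library and 8.17% (7.65 to 8.71) at 12 h, a ratio of 2.16 (1.93 to 2.42). The ratio was 1.11 (0.980 to 1.27) at 24 h and 1.31 (1.16 to 1.47) at 96 h, and with the stricter filter these 3 ratios were 3.45, 2.67 and 5.27. With each library clustered on its own the ratio at 24 h was 0.807, the opposite direction. The T-like ratio was 0.691 (0.657 to 0.727) at 12 h, 0.779 (0.743 to 0.817) at 24 h and 1.58 (1.52 to 1.64) at 96 h. The stricter filter gave 1.42 at 12 h and 1.10 at 24 h, the opposite direction, and 3.40 at 96 h. B-like cells held 31.8%, 33.9%, 28.3% and 34.5%, with ratios between 0.888 and 1.08. Their ratio at 12 h was 0.980 without a cell filter, and with the stricter filter the ratios were 1.28, 0.665 and 1.90. Dendritic cell-like cells held 0.922%, 0.988%, 0.599% and 0.760%, and plasma cell-like cells 0.228%, 0.202%, 0.129% and 0.147%. The 2 clusters left without a name held 0.509%, 0.816%, 0.599% and 0.760%, and the larger of them was led by the proliferation genes Top2a and Mki67.

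**Figure D1:**
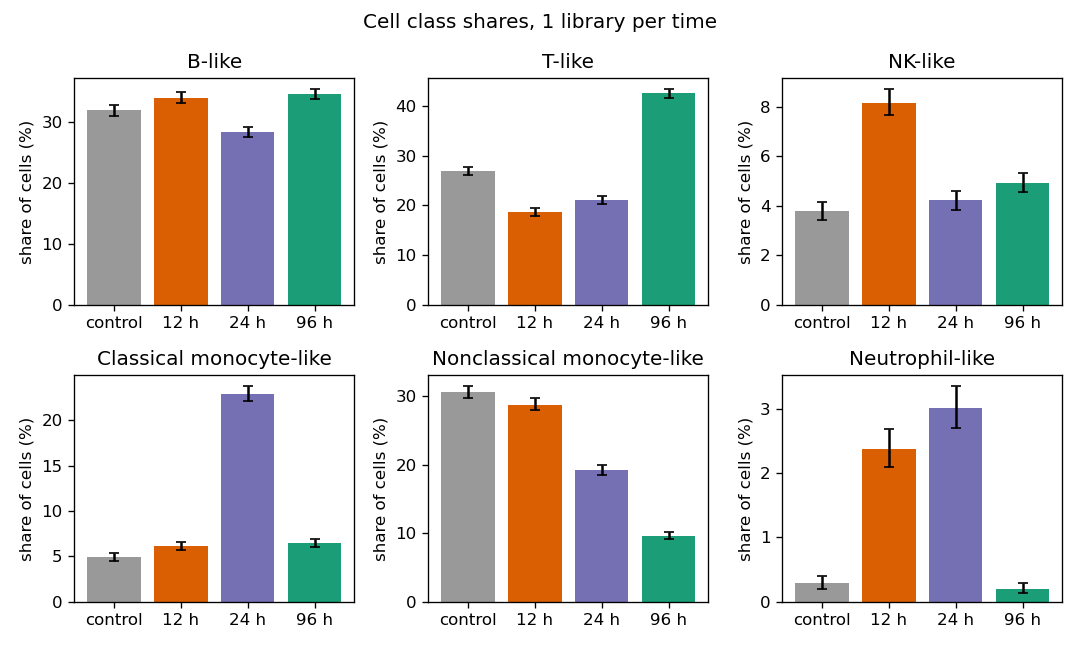
Share of the cells used (%, vertical axis) held by 6 cell classes in the control library and in the libraries of 12, 24 and 96 h. Bars are the shares of 1 library each and error bars the exact 95% binomial intervals, which cover counting error only. The classical monocyte-like bar stands at 4.91% in the control library and at 22.98% at 24 h, and the T-like bar at 42.5% at 96 h.

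At 12 h, classical monocyte-like cells differed more from their control than any other class compared, with proliferation genes and the calprotectin genes higher and class II antigen presentation and immediate early genes lower. S100a8 and S100a9, which encode the calprotectin subunits, stood at 19110 and 12280 CPM against 417 and 53.6 in the control library. Of 2550 genes, 272 were at least 2-fold higher and 183 at least 2-fold lower. The stricter cell filter left too few classical monocyte-like cells for gene values, so their gene results were not checked under it. These cells came mostly from cluster 24 at 12 h (550 cells), whereas the control cells came from cluster 17 (552 cells), and the median cell held 14833 UMIs against 7612. A cluster held by 1 library can reflect that library as much as a cell state.

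The cell cycle list held 11 measured members in the 12 h classical monocyte-like cells, of which 9 were at least 1.5-fold higher and 0 lower. Its median log2 ratio was 3.79, at percentile 100 among random expression-matched lists, a description of these libraries as for every list below. With at least 100 UMIs asked of a member the median was 4.51. Stmn1, a microtubule regulator of dividing cells, stood at 211 CPM against 7.17, a ratio of 29.4 (20.8 to 43.1). Mki67 stood at 55.7 against 4.03. Cdk1, the mitotic kinase, stood at 15.7 against 0.224 from 1 UMI, a ratio of 69.9 (12.3 to 2778). Pcna, the replication clamp, was the lowest member at 0.752 (0.650 to 0.871). Among single genes, Cdkn3, a phosphatase of cyclin-dependent kinases, was 72.8 times higher (36.9 to 169), and Spc24, a kinetochore protein, 66.0 times higher (25.7 to 243). Fetub, a fetuin, had 0 UMIs in the control library and 81.5 CPM (75.9 to 87.4) at 12 h. That is a ratio of 121 against a floor of 3 counts, with an exact lower bound of 98.4.

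The oxidative phosphorylation list had 8 of 10 members at least 1.5-fold higher in these cells, with a median log2 ratio of 1.03 (percentile 99.9) and Uqcrq, a complex III subunit, at 2.93 (2.74 to 3.14). The glycolysis and hypoxia list had 8 of 13 higher and 2 lower, with a median of 0.76 (percentile 99.8). Eno1, a glycolytic enolase, was 2.48 times higher (2.36 to 2.60), and Vegfa stood at 0.104 CPM from 1 UMI against 12.99. The neutrophil granule list had 3 of 6 higher with a median of 1.14 (percentile 99.7). That median was 2.22 without a cell filter, 1.76 with cells clustered on marker genes only and 0.33 when at least 100 UMIs were asked of a member. Lcn2, a siderophore-binding granule protein, had 0 UMIs in the control library and a ratio of 34.3 against the floor (exact lower bound 27.7). It stood at 23.1 CPM, only 1.88% of its level in the class where it was highest.

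Class II genes carry rat names here, and a list under those names was added after the data were seen. In the 12 h classical monocyte-like cells 9 of its 9 measured members were at least 1.5-fold lower, with a median log2 ratio of -3.06 (percentile 0), and -2.25 when cells were clustered on marker genes only. RT1-Bb, a class II beta chain, stood at 44.7 CPM against 812, a ratio of 0.0550 (0.0497 to 0.0609), and 0.0908 with marker genes only. RT1-Da stood at 298 against 2857. Cd74, the invariant chain, stood at 546 against 4722. The list under mouse names had only Cd74 and Ciita measured, too few for a median. In the immediate early list, genes transcribed within minutes of a stimulus, 12 of 13 members were lower and 1 was higher, with a median of -1.35 (percentile 0). Egr1 stood at 23.2 against 516 CPM, a ratio of 0.0449 (0.0389 to 0.0515), with 0.0242 when doublets were kept, 0.0256 at a higher clustering resolution and 0.0760 as a mean over cells. Fosb stood at 11.3 against 190. Jun was the exception at 1.90 (1.68 to 2.15).

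Type I interferon response genes were also lower in the 12 h classical monocyte-like cells, 10 of 14 by at least 1.5-fold and 1 higher, with a median log2 ratio of -1.28 (percentile 0), and -0.70 with cells clustered on marker genes only. Mx1, an antiviral GTPase, stood at 6.89 against 44.6 CPM. Oas1a, a sensor of double-stranded RNA, went the other way at 71.5 against 4.71, and stood at 15.8% of its level in the class where it was highest. NF-kB targets had 6 of 10 lower and 0 higher, with a median of -0.73 (percentile 0.15). Glucocorticoid response genes had 6 of 9 lower and 2 higher, with a median of -0.96 (percentile 0.03). Il1r2, the interleukin-1 decoy receptor, had the largest ratio in that list at 258 against 13.4 CPM, a ratio of 19.2 (14.8 to 25.2). The acute inflammation list was split, 6 of 15 higher and 5 lower, with a median of -0.28 (percentile 4.21). Chemokine receptors and adhesion genes had a median of 0.33 (percentile 79.2), with Cxcr2, a receptor of neutrophil chemoattractants, at 19.3 against 0.224 CPM from 1 UMI and Cx3cr1 at 0.246 (0.175 to 0.341).

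Nonclassical monocyte-like cells at 12 h showed higher levels of genes of lipid-handling and debris-clearing macrophages and lower levels of immediate early genes. Gpnmb, a glycoprotein of phagocytes, stood at 64.4 CPM (60.1 to 68.9) against 8.71 (7.17 to 10.5), a ratio of 7.39 (6.06 to 9.09). Il18, an interferon-inducing cytokine, was 5.53 times higher (4.58 to 6.72), or 2.63 times with the stricter filter, and Rgs1, a brake on chemokine receptor signalling, 4.11 times higher (3.92 to 4.31). Jund, Cdc42ep4 and Arl5b stood at ratios of 0.343, 0.362 and 0.343. Of 2711 genes, 41 were at least 2-fold higher and 23 lower. Most of these cells at 12 h lay in cluster 2 (1898 cells) and most control cells in cluster 0 (3179 cells). Fn1, a marker that named the classical monocyte-like class, stood at 630 against 215 CPM in them, and at 35.35 against 32.6 in B-like cells. Lyz2, another such marker, stood at 15930 against 13680 in the nonclassical monocyte-like cells.

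In the list of alternative activation and efferocytosis 7 of 9 members were at least 1.5-fold higher in the 12 h nonclassical monocyte-like cells, with a median log2 ratio of 2.89 (percentile 100). The complement genes C1qa and C1qb stood at 16.5 and 18.8 CPM against 0 UMIs, ratios of 70.8 and 80.5 against the floor, with exact lower bounds of 57.1 and 65.0. Apoe, a lipid carrier, stood at 16.9 against 2.64. This median was 0.88 with doublets kept, 0.82 at a higher clustering resolution, 1.85 with cells clustered on marker genes only and -0.20 with the stricter filter, and the Gpnmb ratio was 2.94, 3.05, 2.96 and 0.779. The immediate early list had 7 of 13 lower and 0 higher, with a median of -0.63 (percentile 0). NF-kB targets had a median of -0.38 (percentile 0), with 3 of 10 lower and 2 higher. Interferon response genes had a median of 0.26 (percentile 99.9). With the stricter filter these last 3 medians were -1.03, -0.64 and 0.12. S100a8 stood at 480 CPM in these cells and at 590 in B-like cells of the same library, so its level here was not above that of a class that should lack it.

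T-like cells at 12 h showed higher cytotoxic and activation genes and lower immediate early genes. Batf, a transcription factor of activated T cells, was 2.67 times higher (2.36 to 3.03), the interferon-induced GTPase Ifi47 2.43 times (2.12 to 2.78) and the integrin chain Itgb1 2.24 times (2.11 to 2.39). With the stricter filter Batf was 1.46 times higher and Itgb1 1.32 times. Jun stood at 13.5 against 64.2 CPM, a ratio of 0.210 (0.176 to 0.249), and 0.768 with the stricter filter. Dnaaf2 stood at 0.234 and Txnip, a thioredoxin inhibitor, at 0.482. Of 2038 genes, 24 were at least 2-fold higher and 10 lower. The number at least 2-fold from control was 90 with the stricter filter and 22 without T cluster 5. Median-of-ratios scaling moved all log2 ratios by -0.11 here. Cluster 4 was the largest T-like cluster at 12 h and cluster 14 in the other libraries.

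Cytotoxic effectors had 7 of 9 members at least 1.5-fold higher in the 12 h T-like cells, with a median log2 ratio of 1.61 (percentile 100). Ccl5, a chemokine of cytotoxic cells, stood at 1584 CPM against 187, a ratio of 8.47 (8.14 to 8.80), while B-like cells held 136 and 92.1. T cluster 5, whose leading genes include the cathepsin Ctsw and the killer-cell receptor Klra22, held 10.8% of T-like cells at 12 h and 1.66% in the control library. Without it the median was 0.38, and at a higher clustering resolution 0.90. T cell activation and checkpoint genes had 5 of 10 higher with a median of 0.56 (percentile 100). Lag3, an inhibitory receptor, was 2.29 times higher (2.04 to 2.59). Cell cycle genes had 5 of 9 higher with a median of 0.60 (percentile 99.6). These last medians were -0.29 and -0.43 with the stricter filter, and the cell cycle median was 0.20 when at least 100 UMIs were asked of a member. Immediate early genes had 8 of 12 lower with a median of -0.74 (percentile 0), and glucocorticoid response genes 4 of 9 lower with a median of -0.45 (percentile 0), and -0.81 with the stricter filter. S1pr1, the receptor that lets lymphocytes leave lymphoid organs, stood at 0.496 (0.474 to 0.519) in the naive and recirculating list, whose median was -0.16 (percentile 1.15). That median was -0.50 with the stricter filter, -0.27 with median-of-ratios scaling and -0.056 without T cluster 5.

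NK-like cells at 12 h carried lower levels of proliferation genes. Among single genes, Ly49i4 was 2.41 times higher (2.05 to 2.85), Klra22 2.66 times (1.95 to 3.69; 1.56 times with cells clustered on marker genes only) and the lysophosphatidic acid receptor gene Lpar6 2.10 times (1.69 to 2.63). Genes of such receptor families share sequence, so their counts may be split between members. Stmn1 stood at 0.368 (0.315 to 0.430), Ldhb at 0.440 and Prim1, a DNA primase subunit, at 0.431. Cell cycle genes had 4 of 8 lower and 0 higher, with a median log2 ratio of -0.70 (percentile 0). Immediate early genes had a median of -0.46 (percentile 0), and cytotoxic effectors of -0.04 (percentile 20.5). Of 2471 genes, 11 were at least 2-fold higher and 11 lower. The unnamed cluster of proliferating cells is outside both the T-like and the NK-like class.

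B-like cells at 12 h held lower levels of immediate early genes, a list with 5 of 12 members at least 1.5-fold lower, with a median log2 ratio of -0.57 (percentile 0) and Egr1 at 15.9 against 44.9 CPM. This list was at percentile 0 in every class compared at 12 h. A shift of the whole library therefore cannot be told apart from a change in each class. The adenine nucleotide carrier Slc25a4 was 1.97 times higher (1.77 to 2.19), B3gnt5 1.82 times and Gpr171 1.79 times. Chrne stood at 0.272 (0.229 to 0.321), the kinase gene Map3k8 at 0.370 (0.350 to 0.390) and the lipid receptor gene Gpr132 at 0.379. B cell activation genes had a median of -0.22 (percentile 1.78), the class II list under rat names of -0.41 (percentile 0) and oxidative phosphorylation genes of 0.26 (percentile 99.8), or 0.17 with median-of-ratios scaling. The B cell activation median was -0.0014 without a cell filter, -0.13 with cells clustered on marker genes only and -0.11 when at least 100 UMIs were asked of a member. Of 2495 genes, 5 were at least 2-fold higher and 8 lower. These counts had no guard against free RNA. The higher genes included S100a8, at 590 CPM against 9.62, and S100a9, at 351 against 6.04, which B cells should lack. S100a8 entered the 12 h counts of T-like cells (376 against 4.78) and NK-like cells (484 against 2.28) as well. Erythroid and platelet genes were higher in these cells too, with medians of 1.86 and 1.05, as they were in all cells of the 12 h library at 2.06 and 1.09. No immunoglobulin constant gene of the fixed list was measured under its listed name.

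At 24 h, classical monocyte-like cells held higher levels of inflammatory mediator genes and NF-kB targets and lower levels of interferon response and class II genes. Acod1, which makes the antimicrobial metabolite itaconate, stood at 61.2 CPM (58.3 to 64.3) against 0.448 (0.0543 to 1.62) from 2 UMIs, a ratio of 137 (37.8 to 1129). This ratio was 66.6 with cells clustered on marker genes only, 70.6 without a cell filter and 87.7 as a mean over cells. Il1b, a fever-inducing cytokine, stood at 550 against 122, a ratio of 4.52 (4.15 to 4.94). Cxcl2, a neutrophil chemoattractant, stood at 243 against 35.4, a ratio of 6.87 (5.87 to 8.10). Of 2413 genes, 108 were at least 2-fold higher and 51 lower. The cells came from clusters 3 (1688 cells) and 17 (793 cells), and 91 genes were at least 2-fold from control without clusters 3 and 24.

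Among single genes in these cells, the metallothionein Mt2A was 12.1 times higher (9.47 to 15.8) and 21.7 times with cells clustered on marker genes only. Ehd1, an endosomal recycling ATPase, was 8.30 times higher (7.16 to 9.68). Without clusters 3 and 24, Acod1 was 4.55 times higher, Ehd1 3.31 times and Mt2A 18.9 times. RT1-Bb stood at 0.102 (0.0966 to 0.108), RT1-Db1 at 0.148 (0.143 to 0.154) and RT1-Da at 0.155 (0.151 to 0.159). The RT1-Db1 ratio was 0.0987 at a higher clustering resolution.

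The acute inflammation list had 10 of 16 members at least 1.5-fold higher and 1 lower in the 24 h classical monocyte-like cells, with a median log2 ratio of 1.08 (percentile 100). The member that was lower was Il1r2 at 0.292 (0.210 to 0.409). NF-kB targets had 6 of 10 higher and 0 lower, with a median of 0.96 (percentile 100), and 0.41 without clusters 3 and 24. Tnfaip3, a feedback inhibitor of NF-kB, stood at 23.3 against 5.38 CPM, and Nfkbia at 1697 against 590. Interferon response genes had 12 of 14 lower with a median of -1.03 (percentile 0). Ifit3 stood at 5.82 against 37.2 CPM and Mx1 at 5.51 against 44.6. The class II list under rat names had 9 of 9 lower with a median of -2.67 (percentile 0). Glucocorticoid response genes had 5 of 10 lower and a median of -0.56 (percentile 0.05), yet Fkbp5, a chaperone induced through the glucocorticoid receptor, stood at 102 against 14.1. The neutrophil granule list had a median of 0.93 (percentile 99.8), 0.57 with cells clustered on marker genes only and 0.34 without clusters 3 and 24. Mmp8 in that list stood at 7.39 CPM, 0.504% of the neutrophil level. The median of the cell cycle list was 0.02 (percentile 68.0).

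Nonclassical monocyte-like cells at 24 h shared lower interferon response levels and had much higher levels of Fkbp5 and Rgs1. Fkbp5 stood at 138 CPM (130 to 146) against 8.32 (6.82 to 10.1), a ratio of 16.6 (13.6 to 20.4). Rgs1 was 8.43 times higher (8.06 to 8.83), and 5.16 times with cells clustered on marker genes only. Pcsk1, a prohormone convertase, was 7.91 times higher (6.33 to 9.99), and 3.55 times with the stricter filter. Mx1 stood at 15.3 against 112, a ratio of 0.137 (0.114 to 0.163), and Irf7, a master regulator of interferon responses, at 0.224 (0.191 to 0.262), or 0.133 with marker genes only. Fxyd2 stood at 0.202 (0.161 to 0.252), and 0.520 with marker genes only. Of 2737 genes, 33 were at least 2-fold higher and 27 lower, from cells mostly of cluster 1 (1455 cells).

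In the 24 h nonclassical monocyte-like cells 12 of 15 interferon response genes were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.84 (percentile 0), and -1.44 with cells clustered on marker genes only. The class II list under rat names had 9 of 10 lower with a median of -1.36 (percentile 0), -2.10 at a higher clustering resolution and -0.79 with doublets kept. Acute inflammation genes had 7 of 15 higher with a median of 0.53 (percentile 100), and 0.96 with marker genes only. Its top member S100a8 stood at 336 CPM, below the 439 of B-like cells, whereas Il1b stood at 305 against 197, a ratio of 1.55 (1.47 to 1.64). NF-kB targets had a median of -0.04 (percentile 22.2) and glucocorticoid response genes of -0.35 (percentile 0.02), with 3 of 10 higher and 2 lower, and -0.64 with marker genes only.

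Lymphocytes at 24 h also held lower interferon response levels, and T-like and NK-like cells higher Fkbp5. The interferon list had 9 of 15 members at least 1.5-fold lower in B-like cells, with a median log2 ratio of -0.70 (percentile 0). In T-like cells 5 of 14 were lower with a median of -0.45 (percentile 0.13), and in NK-like cells 4 of 12 with a median of -0.33 (percentile 0.43), or -0.22 when at least 100 UMIs were asked of a member. The interferon list was thus below the bounds of random lists in every class compared at 24 h. A difference of the whole 24 h or control library cannot be told apart from a change in each class. Fkbp5 was 3.52 times higher (3.16 to 3.94) in T-like cells and 3.25 times (2.60 to 4.09) in NK-like cells. Yet the glucocorticoid response list, which includes Fkbp5, had medians of -0.35 (percentile 1.12) in T-like and -0.23 (percentile 2.15) in NK-like cells. The NK-like median was -0.12 with cells clustered on marker genes only. In T-like cells Oaf was 3.80 times higher (3.30 to 4.39) and the metallothionein Mt1 2.89 times (2.70 to 3.09), ratios of 1.56 and 1.59 with the stricter filter, which put Fkbp5 at 6.38. Stom stood at 0.443, Lgals9 at 0.448 (0.399 to 0.502) and Jun at 0.455 (0.406 to 0.509), and with the stricter filter Lgals9 stood at 1.06 and Jun at 1.76. Of 1920 genes in T-like cells, 9 were at least 2-fold higher and 14 lower. Median-of-ratios scaling, which moved all log2 ratios by 0.13, gave 13 and 10. With the stricter filter 112 genes in T-like cells were at least 2-fold from control.

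NF-kB targets in T-like cells at 24 h had 4 of 10 members at least 1.5-fold higher and 1 lower, with a median log2 ratio of 0.40 (percentile 100; 0.12 with the stricter filter) and Bcl3, an inhibitor family member, at 3.39 (2.55 to 4.56). Activation and checkpoint genes had a median of 0.33 (percentile 100; 0.52 with the stricter filter), with Foxp3, the regulatory T cell factor, at 0.534 (0.450 to 0.632). The cell cycle median of 0.41 (percentile 99.9) was -0.10 without T cluster 5 and -0.11 with cells clustered on marker genes only. It was 0.22 with the stricter filter, 0.12 without a cell filter, 0.099 with doublets kept, 0.019 as a mean over cells and 0.0060 when at least 100 UMIs were asked of a member. Cytotoxic effectors had a median of -0.30 (percentile 5.85). In NK-like cells Plek was 1.81 times higher (1.69 to 1.95) and Tg 2.21 times (1.61 to 3.08), while Rgs2, Ldhb and the class I gene RT1-A1 stood at 0.403, 0.452 and 0.553. Their cell cycle list had a median of 0.36 (percentile 99.8), and 0.22 as a mean over cells. In B-like cells Acer3, an alkaline ceramidase, was 2.74 times higher (2.57 to 2.93), the carbonic anhydrase Car2 2.30 times and Evi2a 1.82 times. Tagln2 stood at 0.475, Mx1 at 0.458 and Insig1, a brake on sterol synthesis, at 0.452 (0.401 to 0.509). The naive and recirculating list had a median of -0.46 (percentile 0.28) in B-like cells. Platelet genes were higher in these cells with a median of 1.14 (percentile 99.9), and Lyz2, a monocyte gene, stood at 1092 CPM against 528. The counts of genes at least 2-fold higher and lower were 8 and 8 in B-like cells and 7 and 8 in NK-like cells.

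**Figure D2:**
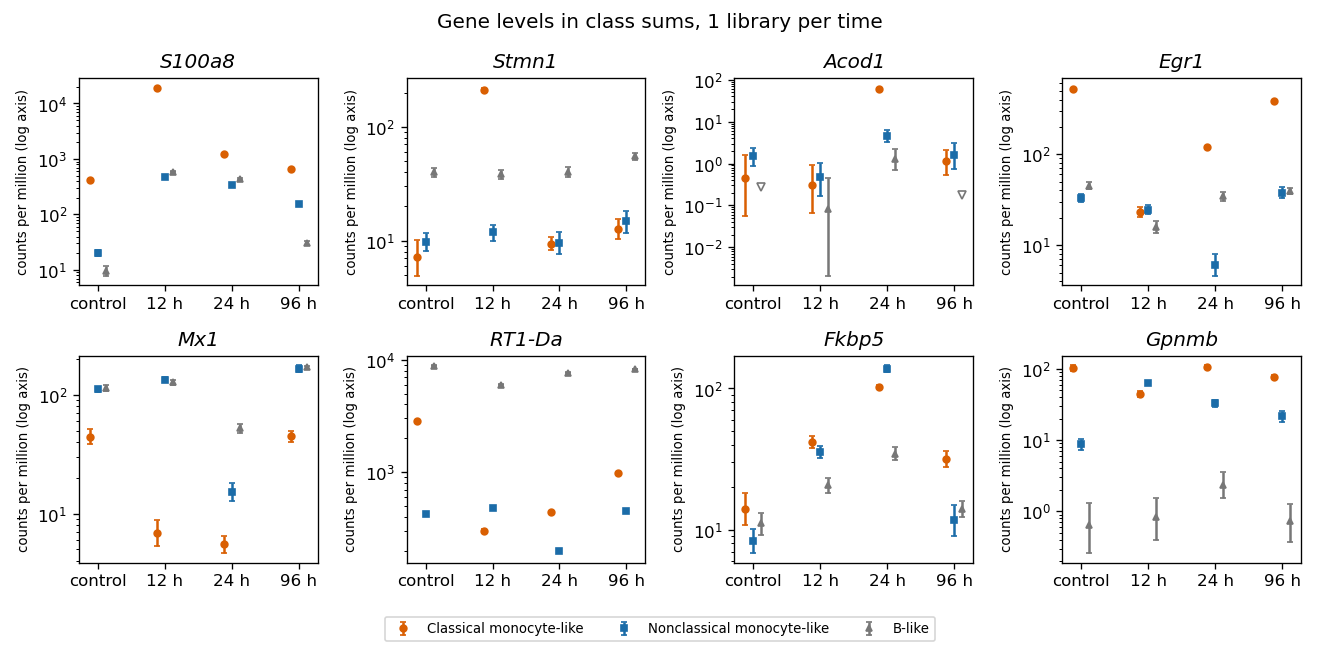
Levels of 8 genes (CPM, log axis) in classical monocyte-like, nonclassical monocyte-like and B-like cells of the control library and the libraries of 12, 24 and 96 h. Points are class sums of 1 library each, error bars exact 95% Poisson intervals for counting error only, and open triangles mark 0 UMIs, drawn at the floor of 3 counts. S100a8 in classical monocyte-like cells stands at 19110 at 12 h against 417 in the control library, and Fkbp5 in nonclassical monocyte-like cells at 138 at 24 h against 8.32.

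At 96 h, heat shock genes were higher in lymphocytes and nonclassical monocyte-like cells and class II genes lower in classical monocyte-like cells. In classical monocyte-like cells 5 of 2355 genes were at least 2-fold higher and 10 lower. The mitochondrial carbonic anhydrase gene Ca5b was 3.92 times higher (3.22 to 4.81), Upp1, a uridine phosphorylase, 3.31 times (2.75 to 4.01) and Mrpl43 2.28 times (1.86 to 2.81). RT1-Bb stood at 0.143 (0.133 to 0.154), and 0.217 with cells clustered on marker genes only. RT1-Db1 stood at 0.330 (0.317 to 0.344) and Fosb at 0.180 (0.157 to 0.207). The class II list under rat names had 6 of 9 members at least 1.5-fold lower with a median log2 ratio of -1.33 (percentile 0), -0.80 with marker genes only and -0.84 with doublets kept. Both libraries' cells came mostly from cluster 17, 809 of them at 96 h. Interferon response genes had a median of 0.10 (percentile 65.0) and NF-kB targets of -0.20 (percentile 0.23). In the acute inflammation list 4 of 14 members were higher and 3 lower.

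Nonclassical monocyte-like cells at 96 h had 8 of 2665 genes at least 2-fold higher and 4 lower, from cells mostly of cluster 0 in both libraries. The number at least 2-fold from control was 19 with the stricter filter and 23 with cells clustered on marker genes only. Ca5b was 4.07 times higher (3.65 to 4.53), Upp1 2.47 times (2.14 to 2.85) and Cd8a, a coreceptor chain, 3.74 times (3.55 to 3.94), at 680 CPM against 182. The Cd8a level was not particular to 96 h, as it stood at 737 CPM in the nonclassical monocyte-like cells of 24 h. Cxcl16, a membrane-bound chemokine, stood at 14.1 against 91.5, a ratio of 0.154 (0.121 to 0.193). Fxyd2 stood at 0.374 and Cd22 at 0.442. Interferon response genes had 5 of 16 members at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.38 (percentile 100), and Ifit3 stood at 339 against 193. The class II list had a median of -0.09 (percentile 9.74), and the alternative activation list of 0.00 (percentile 46.7). With the stricter filter Ca5b was 2.30 times higher.

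The heat shock list had 3 of 7 members at least 1.5-fold higher and 0 lower at 96 h in B-like, T-like and nonclassical monocyte-like cells, with median log2 ratios of 0.38, 0.39 and 0.43 (percentile 100 in each). In NK-like cells 2 of 7 were higher with a median of 0.39 (percentile 100). With the stricter filter the T-like median was -0.12 and the nonclassical monocyte-like median 0.71. Hsph1, a heat shock protein of the 110 family, stood at 57.7 against 21.4 CPM in NK-like cells, a ratio of 2.69 (1.96 to 3.77), and Dnaja1, a co-chaperone, at 284 against 128. In classical monocyte-like cells the list had 0 members past 1.5-fold and a median of 0.14 (percentile 83.6).

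In T-like cells at 96 h, 2 of 1949 genes were at least 2-fold higher and 2 lower, and 3 and 1 with median-of-ratios scaling. The number at least 2-fold from control was 75 with the stricter filter. It was 2 with doublets kept, at a higher clustering resolution or without T cluster 5. Saraf, a brake on store-operated calcium entry, was 1.69 times higher (1.59 to 1.80), Ei24 1.65 times and Dnaja1 1.61 times. Ldhb, a lactate dehydrogenase subunit, stood at 0.625, Stom at 0.605 and Hif1a, the hypoxia factor, at 0.613 (0.571 to 0.658). Cytotoxic effectors had 3 of 9 higher with a median log2 ratio of 0.33 (percentile 100), -0.0094 with the stricter filter, 0.058 at a higher clustering resolution and -0.04 without T cluster 5, which held 5.60% of T-like cells. Activation and checkpoint genes had a median of -0.26 (percentile 0.18; -0.61 with the stricter filter), with Foxp3 at 10.8 against 26.0 CPM. Erythroid genes were higher in T-like cells with a median of 0.74 (percentile 99.9), and platelet genes lower in B-like cells with a median of -0.76 (percentile 1.14). In NK-like cells Cd7 was 2.19 times higher (1.82 to 2.65), while the galectin gene Lgals1 stood at 0.495, Ppt1 at 0.491 and RT1-A1 at 0.612. Most NK-like cells at 96 h lay in cluster 7, and in the other libraries in cluster 6. Their cell cycle median was -0.35 (percentile 0.22), with -0.997 when cells were clustered on marker genes only, -0.19 with doublets kept and -0.20 without a cell filter. In these cells 7 genes were at least 2-fold higher and 4 lower. In B-like cells the cathepsin Ctsh was 2.12 times higher (2.01 to 2.23), Fam129c 1.95 times and Tifa 1.89 times. Fam129c is among the leading genes of B-like cluster 23, which held 2.36% of B-like cells (1.94 to 2.85) at 96 h and 0.110% in the control library. Without that cluster Fam129c was 1.78 times higher and Tifa 1.18 times. RT1-Bb stood at 0.529 (0.519 to 0.539), Hnrnpa3 at 0.544 and Camk2d at 0.565. In B-like cells 1 gene was at least 2-fold higher and 1 lower, and 1 and 3 with median-of-ratios scaling. B cell activation genes had a median of -0.25 (percentile 2.03), with -0.15 under marker genes only and -0.094 when at least 100 UMIs were asked of a member.

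**Figure D3:**
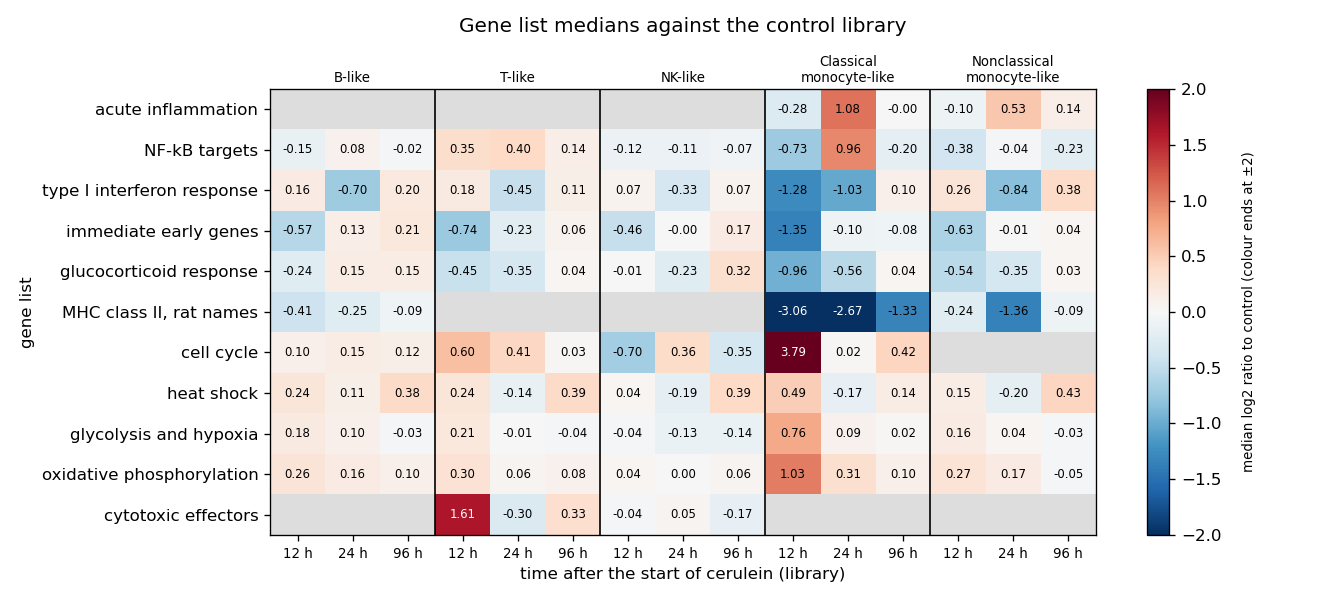
Median log2 ratio to the control library for 11 gene lists (vertical axis) in 5 cell classes at 12, 24 and 96 h (horizontal axis), 1 library per time. Red is higher and blue lower, the number in each cell is the median, and grey marks lists that were not assigned to that class and so not computed. The cell cycle list stands at 3.79 in classical monocyte-like cells at 12 h, and the interferon list is below 0 in all 5 classes at 24 h.

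Of the 178 combinations of a list, a class and a time with at least 3 measured members, 86 had a median outside the central 95% of random lists. Endothelial genes in all cells had medians of 0.42, -0.01 and -0.05 (percentiles 91.6, 70.2 and 47.6), inside those bounds. Only 2 acinar genes were measured, too few for a median. The neutrophil-like class, with 32 control cells, was below the 50 cells asked of a class and was not compared gene by gene.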

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

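All tests in this part except that of shallow cells were chosen after the result was seen. The differences between times or classes given here were not tested, because each rests on 1 library per group. They stand out because medians outside the bounds of random lists pointed in opposite directions. NF-kB targets in classical monocyte-like cells had a median log2 ratio of -0.73 at 12 h and 0.96 at 24 h. Clusters 24 and 3, held almost wholly by 1 library each, made up most of those cells, and without them the 24 h median was 0.41. Cell cycle genes in NK-like cells had -0.70 at 12 h and 0.36 at 24 h. Interferon response genes in nonclassical monocyte-like cells had -0.84 at 24 h and 0.38 at 96 h. At 12 h the cell cycle median was -0.70 in NK-like cells and 3.79 in classical monocyte-like cells. The unnamed cluster led by Top2a and Mki67 lies outside the NK-like class, whereas cluster 24 stayed within the classical monocyte-like class. That unnamed cluster held 57 control cells, 73 at 12 h and 65 at 24 h. Both cell cycle contrasts may thus partly reflect how dividing cells were assigned to classes.

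A small cell group outside the comparisons was larger at 96 h. Basophil or mast cell-like cells numbered 21 at 96 h, 0.163% of cells (0.101 to 0.249), and 0 in the control library, which at a floor of 3 counts allows a share of up to 0.0264%, and 0.0324% by the exact binomial interval.

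Cell cycle genes stood higher in classical monocyte-like cells at 12 h, whose median cell was deeper than in the control library. Doublets with lymphocytes are argued against by Cd3e, Cd79b and Nkg7, which reached at most 1.32% of the level of their own class. A share of cells was taken with a UMI of Mki67, Top2a, Stmn1, Birc5 or Cdk1, without the other members of the list such as Pcna and Tubb5. After thinning each cell to 2000 UMIs, this share was 25.4% at 12 h and 1.97% in the control library (59.6% and 9.12% unthinned). Detection in deeper cells therefore does not account for the difference in that share, for these genes. In the 62 cells at 12 h with at most 7612 UMIs, the median was -0.015 over 4 measured members. The same members had a median of 2.12 in all 12 h cells. The value was under the bound set beforehand, the outcome predicted if depth were the cause. Stmn1 stood at 21.8 CPM against 7.17 and Tubb5 at 84.3 against 165, so members went both ways. The rule set beforehand looked at the median only, and weighing split members was not part of it. Shallow cells may not stand for cluster 24, whose median cell at 12 h held 15430 UMIs, so the test cannot separate depth from cell type. Depth stays open, since dividing cells may hold more RNA or deep cells may be a separate cell type of 1 library.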

How the results depend on the processing

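T-like cells without cluster 5, B-like cells without cluster 23 and classical monocyte-like cells without clusters 3 and 24 were chosen after the results were seen. Of 150 share ratios under alternatives 110 stayed within their interval, 34 moved and 6 reversed. Of 731 list medians 611 stayed, 110 moved and 10 reversed. A list median counted as stayed when it changed by less than the standard deviation of medians of random gene lists of its size. Of 624 ratios of named genes 520 stayed within their counting interval, 101 moved and 3 reversed. That interval is wide at low counts, so Acod1 in classical monocyte-like cells at 24 h counted as stayed at 66.6 against 137. Of 149 counts of genes 104 stayed within 1.5 times and 45 moved. Sums thinned to the smaller total moved 0 of 15 gene counts, platelets kept 0 of 21 share ratios, and totals without haemoglobin, immunoglobulin, mitochondrial and ribosomal genes 0 of 82 list medians. No paired analysis was possible because each group holds 1 library. The cause was not tested for any value below, unless a threshold admits more or fewer genes by construction.

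The stricter cell filter kept 562 control cells, 1749 at 12 h, 1101 at 24 h and 1571 at 96 h. It gave gene values only for T-like and nonclassical monocyte-like cells. The other classes fell under the 50 cells asked of both libraries, B-like cells with 33 in the control library. Gene and list results of B-like, NK-like and classical monocyte-like cells were therefore not checked under this filter. Its share ratios at 12, 24 and 96 h were 1.28, 0.665 and 1.90 for B-like, 1.42, 1.10 and 3.40 for T-like, 3.45, 2.67 and 5.27 for NK-like, 0.782, 0.919 and 0.364 for all monocyte-like, 8.07, 10.6 and 2.74 for classical monocyte-like and 1.09, 1.53 and 0.187 for neutrophil-like cells. Nonclassical monocyte-like cells had 0.510 at 12 h and 0.694 at 24 h. Counts of genes at least 2-fold from control were 90, 112 and 75 in T-like cells and 19 in nonclassical monocyte-like cells at 96 h. In T-like cells the medians were -0.43 for cell cycle and -0.29 for activation at 12 h, and at 96 h -0.0094 for interferon response, -0.12 for heat shock and -0.0094 for cytotoxic effectors. Alternative activation in nonclassical monocyte-like cells at 12 h had -0.20 and Gpnmb 0.779. Lgals9 and Jun in T-like cells at 24 h had 1.06 and 1.76.

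Without a cell filter the share ratios were 0.980, 0.823 and 1.01 for B-like cells, 0.744 at 12 h and 1.66 at 96 h for T-like cells, and at 96 h 0.478 for all and 0.338 for nonclassical monocyte-like cells, with 4 genes in B-like cells at 96 h. With doublets kept, classical monocyte-like ratios were 1.11 at 12 h and 2.46 at 24 h, with 4 genes in B-like and 2 in T-like cells at 96 h. With each library clustered on its own, NK-like cells had 0.807 at 24 h, classical monocyte-like cells 3.23 at 24 h and nonclassical monocyte-like cells 0.710 at 12 h. Clustering on marker genes only gave 1.65, 2.44 and 0.970 for classical and 0.899, 0.839 and 0.357 for nonclassical monocyte-like cells, 18 genes in NK-like and 23 in nonclassical monocyte-like cells at 96 h, and a cell cycle median of -0.11 in T-like cells at 24 h. Resolution 2.0 gave 2 genes in T-like cells at 96 h. A mean over cells and median-of-ratios scaling each gave 4 genes in B-like cells at 96 h.

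A threshold of 10 CPM gave 73, 77 and 35 genes in B-like, 104, 76 and 29 in T-like, 171, 167 and 103 in NK-like, 1038, 385 and 61 in classical and 162, 155 and 42 in nonclassical monocyte-like cells. A threshold of 200 gave 6, 5 and 1, 12, 5 and 1, 6, 4 and 2, 180, 52 and 7, and 21, 25 and 3 in the same order. With at least 100 UMIs per member the class II median under rat names in nonclassical monocyte-like cells at 12 h was 0.042. Without cluster 5, T-like cells had 22 genes at 12 h and 2 at 96 h, a cell cycle median of -0.10 at 24 h and a cytotoxic median of -0.042 at 96 h. Without cluster 23, B-like cells at 96 h had Tifa at 1.18 and RT1-Bb at 0.542. Without clusters 3 and 24 the classical monocyte-like share ratio was 0.0772 at 12 h and 1.51 at 24 h, with 91 genes at 24 h. At 12 h the 39 cells of cluster 17 that were left were too few for gene values.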

Other observations

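All tests in this part were chosen after the result was seen. B-like cluster 23, led by Akap12, Igll1, Vpreb2, Rag1 and Vpreb1, genes of early B cell development, held 105 cells at 96 h and 4 in the control library.

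S100a8 and S100a9 in the 12 h classical monocyte-like cells stood at 22.4% and 17.8% of the neutrophil-like level. Free RNA or doublets from neutrophils would bring other neutrophil transcripts at like shares, but Mmp8, Mmp9 and Retnlg reached at most 1.69%, which argues against that source. A biological difference with pancreatitis stays open as a hypothesis and was not tested beyond the 1 library.

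Gene names in the files include rat names, with 28 RT1- names and 0 H2- names, while the labels give mice. NK cells of mice lack Cd8a, and those of rats carry it. Cd8a in NK-like cells stood at 1.06 times its level in T-like cells in the library where that ratio was lowest and 1.64 times where it was highest, whereas Cd8b reached at most 0.0549 times and Cd8a in B-like cells at most 0.0558 times. Cd4, carried by monocytes of rats, was at least 3.61 times higher in nonclassical monocyte-like than in T-like cells. These values argue against mouse cells counted on a rat annotation and are consistent with cells of rat origin, a hypothesis that the files alone cannot settle.

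RT1-Bb was lower than control in B-like and classical monocyte-like cells at each time and in nonclassical monocyte-like cells at 24 and 96 h, with 0.933 of control (0.858 to 1.01) in the latter at 12 h. In B-like cells it stood at 0.479, 0.570 and 0.529 of control at 12, 24 and 96 h, while the median of RT1-Ba, RT1-Da, RT1-Db1 and Cd74 was 0.803 at its lowest and 0.969 at its highest. Over all 9 other measured members of the list under rat names the lower quartile was 0.676 at its lowest, which argues against lower class II expression as a whole as the only source, although the list median was lower at 12 h (-0.41) and 24 h (-0.25) and 2 of the 9 members, RT1-Ha at 0.374 among them, were as low as RT1-Bb at 12 h. Other RT1 alleles in the control animals than in the treated animals cannot be told apart from the groups, because each group is 1 library. The ratio of RT1-Bb to RT1-Ba relative to control lay between 0.434 and 0.850 over these classes and times, a spread of 1.96-fold.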
